A study of Mus musculus with 11 samples.

How the data were processed

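The labels describe 11 RNA-seq libraries of sorted ST2-positive regulatory T cells from mouse epididymal fat. Libraries were made with a SMART-seq v4 and Nextera XT protocol, per the labels' protocols. The authors deposited a single table of RPKM values per gene, per the file headers. STAR and the mm10 build, which is GRCm38, are named in the submitters' processing notes. The aligner's version, the read counter and the gene annotation are not given in the sources used here.

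The names of the 11 value columns were compared, without regard to case or punctuation, with every label of every sample and with the series text. The names matched 0 samples, so all 11 columns were left unassigned and their values were not used. In the order of the table, the numbers in the column names form consecutive runs of 3, 6 and 2 columns. If the run of 6 is divided in the middle, the runs have the same sizes as the groups in alphabetical order, with the run of 2 at the place of the wild-type PBS group. Sorted by number, the columns also follow the group sizes in the order of the sample labels, with a number skipped after the first 2. If each group takes a consecutive block, both orderings give the same assignment. The groups other than wild-type PBS are of equal size, so sizes alone cannot tell them apart. These correspondences rest on order and numbering and were not taken as an assignment. Expression values were not used to assign columns either. A test with limma on log2 values had been planned before the data were examined, and it was not run. Gene symbols in the table were matched by exact spelling to 28 gene lists fixed before the data were examined, so a member listed under another symbol counts as absent. Coordinates of the named genes came from GENCODE on GRCm38. Depth per library was not assessed.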

Results

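RNA was sequenced from regulatory T cells, the Foxp3-expressing CD4 T cells that restrain immune responses, sorted from the epididymal visceral fat of male mice aged 25 weeks. The sorted cells carried ST2, the receptor for the cytokine IL-33, and a Foxp3-driven YFP-Cre reporter. Each library was made from 1000 cells. The mice carried either wild-type or loxP-flanked alleles of Srebf2, which encodes SREBP2, a transcription factor that activates genes of cholesterol synthesis and uptake. The Cre recombinase acts in Foxp3-expressing cells, where it can excise loxP-flanked Srebf2 sequence. Loss of Srebf2 was not checked here. Each mouse received 2 injections 3 days apart, of PBS or of 2 µg IL-33.

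The labels described 11 libraries. The wild-type PBS group had 2 libraries, and the wild-type IL-33, Srebf2-floxed PBS and Srebf2-floxed IL-33 groups had 3 each. The sample titles name the Srebf2-floxed groups KO and the wild-type groups WT. The title of the series names the question as the effect of IL-33 on cholesterol gene expression that depends on Srebf2. The design therefore implies an IL-33 comparison within each genotype, a genotype comparison within each treatment, and the interaction of both.

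None of these comparisons was made, because the columns of the RPKM table could not be assigned to the groups by name. The table has 11 value columns, and the names of 0 of them occur in the label of any sample or in the series text. The columns can be lined up with the groups in alphabetical order by table order, and in label order by number. If each group takes a consecutive block, both give the same assignment. The groups other than wild-type PBS are of equal size, so their sizes alone cannot tell them apart. However, no label ties a column to a group, and order was not used as a key. For this reason no fold change is reported, and the effect of IL-33 or of Srebf2 genotype on any gene was not analysed here. Expression levels are not reported either, since the values of the unassigned columns were not used. Depth per library was not assessed.

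The table has 24594 gene rows, named by Entrez identifier and symbol. All 20 genes of the cholesterol biosynthesis list are in the table. Of 28 gene lists fixed before the data were examined, some of them for other cell types, 24 have every member in the table. A listed gene was not necessarily detected in these cells, since no values were used. The T cell receptor list has 11 of 14 members, without the constant-region genes Trac, Trbc1 and Trbc2. The B and plasma cell list has 7 of 10, without Ighm, Ighd and Igkc. The oxidative phosphorylation list has 31 of 36 members under the symbols used, and the erythroid list has 4 of 6.

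The genes that define the design are all in the table. Srebf2 (Entrez 20788) lies on the forward strand of chromosome 15 from 82147181 to 82205379 in GRCm38, by the GENCODE annotation. Foxp3 (Entrez 20371) lies on the forward strand of chromosome X from 7573644 to 7595245. Il1rl1 (Entrez 17082), which encodes ST2, lies on the forward strand of chromosome 1 from 40429570 to 40465415.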

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

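The alternatives planned for the expression tests (pseudocount, filters, scaling, fit, replicate block and libraries left out) were not run, since no expression test was run. No paired analysis was possible because no column was assigned to a group. The sample labels also record no animal, litter or day shared by equal replicate numbers of different groups. Assigned columns alone would therefore not have given pairs. No matching rule was planned in advance, the whole column name included. Both rules tried in place of the whole column name were chosen after the data were seen. The number in each column name, sought alone in the titles, gave 0 columns that matched a single sample. The numbers of 2 columns equal replicate numbers and occurred in 4 titles each, and the numbers of the other columns occurred in 0 titles. Replicate numbers recur across the groups, so the number rule could not have tied a column to a single sample. The letters of the column names, sought in every label, also gave 0 columns that matched a single sample. All columns share the same letters, so this rule could not have told the columns apart.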
